A study of Mus musculus with 18 samples.

How the data were processed

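Per the labels, RNA of tumour tissue was extracted with NucleoSpin columns, pooled from 2 or 3 mice, amplified and labelled as biotinylated cRNA with the Ambion MessageAmp kit, and read on Illumina MouseWG-6 v2.0 arrays. The probe signals are intensity values on a linear scale that the authors deposited without background subtraction and without scaling between arrays, as their values show. The dimmest values and the medians differ from array to array. A separate gene table holds, in an intensity unit named other here because of its decimal commas, the lowest, mean and highest signal of each group and a detection score, made with GenomeStudio 1.9.0 and "Normalization = none" per the file headers. The series matrix values carry the name normalized in the labels but equal the probe signals within 1% for 99.6% to 100% of values on each array, with a ceiling. Their column medians run from 172 in cultured cells to 576 at day 7, no log scale or centring was found in them, and how their probes were chosen is not given in the sources used here. The titles and the descriptions number symptomatic Pfp/Rag2 -/- replicates 2 and 3 in opposite order, and the numbers of the titles are used here. The scanner settings, the arrays' chip numbers and the number of mice behind each brain array are not given in the sources used here either.

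The table of probe signals holds no gene names, so probes were linked to the genes of the gene table by their values. A gene was linked to the 1 to 4 probes whose group mean, lowest and highest signals gave all 24 values of the gene within rounding (largest difference 0.0557 signal units among linked genes, against at least 2.80 for the next best single probe). Of 30854 genes 30279 were linked (98.1%), with 42350 probes, and none of 30854 decoys made by mixing genes was linked to 1 probe. With 946 control probes taken as negative controls, recomputed detection scores matched those of the gene table within 0.0032 in the median of each group. Names were brought to current mouse symbols with the annotation of assembly GRCm38.p6 (16223 by symbol, 5692 by synonym, 8939 left as they were). The order of genes along chromosomes came from the same annotation.

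Signals were background-corrected with the negative control probes and quantile normalized with neqc of limma 3.58.1 (offset 16) in R 4.3.3. Probes with a detection p under 0.01 on at least 2 arrays were kept, and the probe with the highest mean stood for its gene, which left 13726 genes. Where other probes of these genes were called in both directions the number is small for the host comparisons (0, 1 and 2 genes at day 7, day 14 and the symptomatic stage) and 222 of 4213 genes with several probes for cultured cells against brain. All 18 arrays were fitted with 1 mean per group in limma, with moderated t tests (10 residual degrees of freedom, prior 2.99) and Benjamini-Hochberg adjustment over all genes in each of 10 contrasts. A gene is called when its adjusted p is under 0.05, and every gene p-value in the text is limma's. The probe-gene link, figures and tables used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9.

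The text names, in each contrast, from up to 10 genes with the largest rises and 10 with the largest falls among called genes whose groups do not overlap, and from the 4 members of each list with the smallest p. A gene's probe at background on every array of the dimmer side gets a least fold, computed with the dimmer side set to the lowest value of a detected probe on its arrays, and no fold is given where both sides are at background. Medians of lists are of fitted values, those of probes at background included. Lists were tested with camera (preset correlation 0.01, adjusted over the lists of a contrast), with camera under an estimated correlation and with fry. The 27 lists, written before the signals were read, are T cell, NK and cytotoxic effector, B and plasma cell, MHC class I, MHC class II, interferon-gamma response, type I interferon response, checkpoint and immune suppression, macrophage and monocyte, microglia, dendritic cell, neutrophil, neuron, oligodendrocyte, astrocyte, endothelial cell and pericyte, cell cycle, extracellular matrix, hypoxia and glycolysis, complement, chemokine, cholesterol synthesis, immediate early, red blood cell, glioma stem and progenitor, choroid plexus and sex-linked genes. Red blood cell and sex-linked genes, with 1 and 2 measured, were too few to test as lists. Some genes stand in several lists, and tumour cells or brain express many of them.

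The procedure was tried on simulated values drawn from the group means and residual spreads of the measured genes, with 200 genes changed. Of genes changed by 0.5, 1 and 2 (log2) it recovered 10.4%, 55.2% and 90.9% at day 7, 7.46%, 64.2% and 92.4% at day 14, and 16.4%, 70.1% and 98.5% at the symptomatic stage. It called 2, 3 and 4 of 13526 unchanged genes. A list shifted by 0.5 was called in each of the 3, and of 24 unshifted lists 0, 1 and 0 were called. The simulated genes varied independently of each other. These list counts therefore cannot show how often camera calls lists of correlated genes falsely. Alternatives to each step were run 1 at a time: no background correction, offset 50, cyclic loess, median scaling, no detection filter or a strict one, the mean of a gene's probes, only the groups compared, trend and robust moderation, a replicate block, a 2-fold limit, each array left out, and, for tumours, the neuron level as a covariate or, at the symptomatic stage, the oligodendrocyte level. A further alternative, the series matrix values, changed several steps together, with 7715 genes, no scaling and no background correction.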

Results

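RNA from GL261 tumours grown in mouse brain, from cultured GL261 cells and from healthy mouse brain was measured on 18 expression arrays. GL261 is a mouse glioma cell line. The hosts were C57BL/6 wild-type (WT) mice or Pfp/Rag2 -/- mice, which lack perforin, the pore-forming protein of cytotoxic lymphocytes encoded by Prf1, and Rag2, without which no mature T or B cells form. Tumours were taken 7 or 14 days after injection (4 mice per host type at each time, per the labels) or when mice became symptomatic (6 mice per host type), and RNA of 2 or 3 mice was pooled for each array. Each day 7 and day 14 group holds 2 arrays, each symptomatic group 3, healthy brain 2 and cultured cells 2. The median probe signal lay between 67.2 and 134 on the 18 arrays, with medians of the negative control probes from 58.2 to 109, both lowest in cultured cells and highest at day 7. Between 32.3% and 39.8% of probes were detected on an array. Values of replicate arrays correlated at 0.966 to 0.997 across genes, which are not independent replicates. The number of arrays limits the precision of every value. Each p-value of the main fit is measured against a spread shared by all 8 groups, cultured cells and healthy brain included, and not between single mice. Log2 differences between replicate arrays had an SD of 0.19 in healthy brain, 0.25 in cultured cells and 0.25 to 0.59 in tumours.

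The tested probe of Prf1 was detected on every array, at a mean log2 signal of 8.58 (SD 0.09, n = 2) in healthy brain and 9.08 (SD 0.34, n = 2) in cultured cells. In tumours it lay between 7.82 (SD 0.39, n = 2) in WT hosts at day 7 and 8.86 (SD 0.24, n = 3) in symptomatic WT hosts, with 8.11 (SD 0.14, n = 3) in symptomatic Pfp/Rag2 -/- hosts. A second Prf1 probe was detected on 1 array, a day 14 tumour pool of WT hosts, with group means of 5.15 to 5.70 in WT hosts, 4.69 to 4.97 in Pfp/Rag2 -/- hosts, 4.69 in healthy brain and 4.71 in cultured cells. Its values were higher on every WT array than on every Pfp/Rag2 -/- array of the same stage. The Rag2 probe was detected on none of the 18 arrays.

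The pools held brain tissue in amounts that differed with tumour stage. Signals of the neuron list, as a percentage of healthy brain, were 32.4% ± 3.83 (SD, n = 2) in WT hosts and 34.7% ± 14.3 (SD, n = 2) in Pfp/Rag2 -/- hosts at day 7, and 14.1% ± 11.3 (SD, n = 2) and 9.77% ± 9.58 (SD, n = 2) at day 14. At the symptomatic stage they were 2.98% ± 1.08 (SD, n = 3) and 7.07% ± 4.42 (SD, n = 3), and in cultured cells 0.661%. Xist, a transcript of the inactive X chromosome of female cells, stood at 71.6% of healthy brain in WT hosts and 69.2% in Pfp/Rag2 -/- hosts at day 7, at 44.8% and 19.1% at day 14, and at 24.6% and 14.3% at the symptomatic stage. In cultured cells it stood at 0.614%. Signals of choroid plexus genes reached 175% and 49.5% of healthy brain in the pools of Pfp/Rag2 -/- hosts at day 7, against 4.18% and 8.09% in those of WT hosts. The first of those Pfp/Rag2 -/- pools also had the highest log2 signals of Prl (13.70) and Gh (12.90), the pituitary hormones prolactin and growth hormone.

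**Figure D1:**
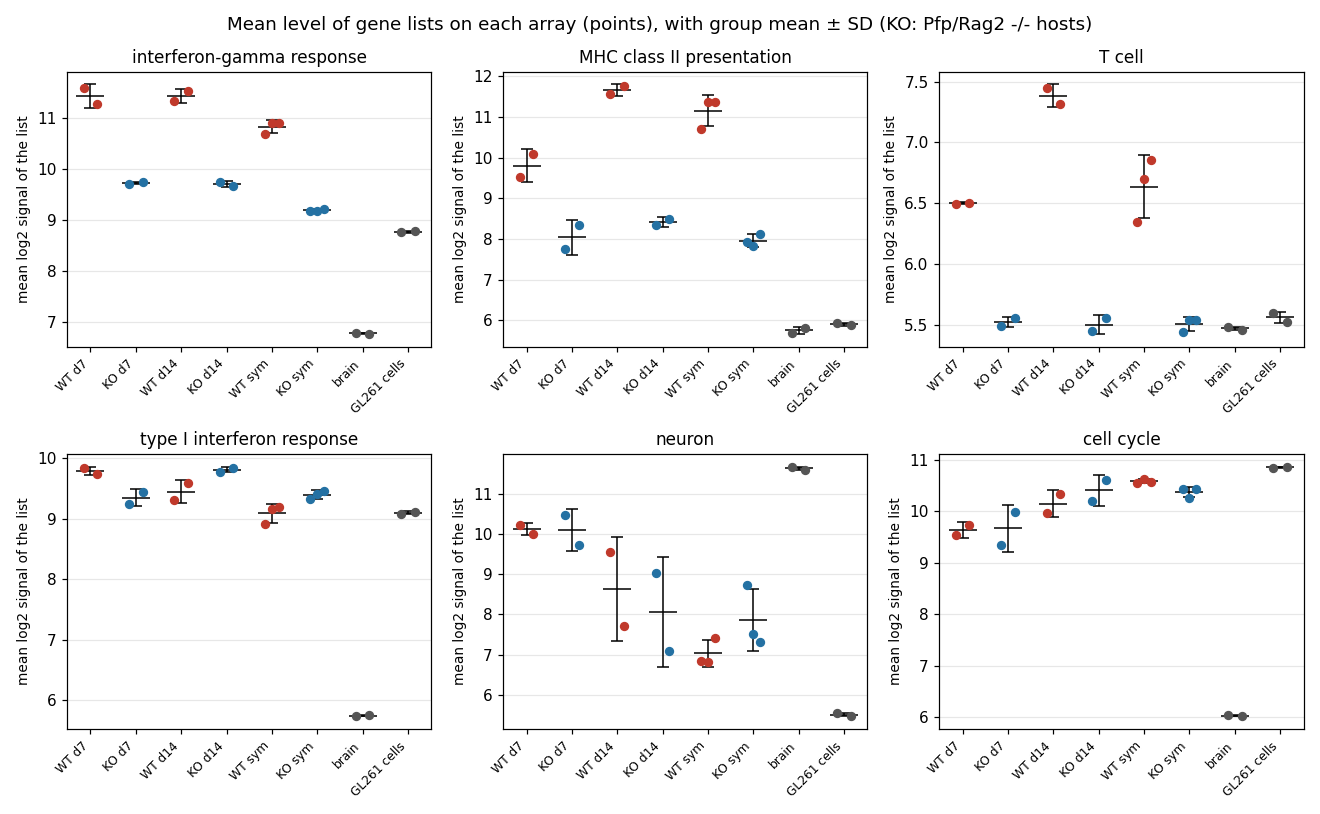
Mean log2 signal of 6 gene lists on each of the 18 arrays (points), by group, with group means (bars). MHC class II genes averaged 11.16 in symptomatic WT hosts, 7.96 in symptomatic Pfp/Rag2 -/- hosts and 5.75 in healthy brain, and neuron genes 11.63 in healthy brain and 7.03 in symptomatic WT hosts.

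The host comparison asks how GL261 tumours in WT mice differ from those in Pfp/Rag2 -/- mice, and it was made at each stage as WT minus Pfp/Rag2 -/-. Changes are given on the log2 scale, or as a least fold where a gene's probe was at background on the dim side, and lists of genes were tested with camera. At day 7 (2 pools per host), tumours of WT hosts held more RNA of interferon-gamma targets, antigen presentation genes and T cell genes. Cxcl9, a chemokine that attracts activated T cells, was higher by 4.67 (SE 0.33, adjusted p = 9.3e-06). The ubiquitin-like modifier Ubd was higher by at least 9.69-fold (adjusted p = 7.3e-06), and the protease inhibitors Serpina3f by at least 10.3-fold (adjusted p = 2.5e-07) and Spint1 by 3.41 (SE 0.44, adjusted p = 7.8e-04). The immune checkpoint ligand Cd274 (PD-L1) was higher by 2.56 (SE 0.15, adjusted p = 2.6e-06). 14 of 16 interferon-gamma response genes rose (16 adjusted over the list alone, adjusted p = 2.5e-32). Gbp2 was higher by 1.69 (SE 0.13, adjusted p = 1.2e-05). 8 of 15 T cell genes rose (10 adjusted over the list alone, adjusted p = 1.4e-12). Cd3d of the T cell receptor complex was higher by at least 3.19-fold (adjusted p = 9.3e-06) and Cd3e by at least 2.46-fold (adjusted p = 5.1e-04). 5 of 9 NK and cytotoxic effector genes rose (7 adjusted over the list alone, adjusted p = 3.7e-11). The granule protein Nkg7 was higher by at least 4.19-fold (adjusted p = 1.7e-04).

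Antigen presentation, chemokine and complement genes were higher in WT hosts at day 7 too. 9 of 16 MHC class I genes rose (13 adjusted over the list alone, adjusted p = 1.9e-18). The immunoproteasome subunit Psmb9 was higher by 1.71 (SE 0.17, adjusted p = 1.2e-04) and the transactivator Nlrc5 by 1.67 (SE 0.17, adjusted p = 1.6e-04). 8 of 10 MHC class II genes rose (10 adjusted over the list alone, adjusted p = 2.2e-16). The class II transactivator Ciita was higher by at least 5.17-fold (adjusted p = 1.5e-05) and the peptide loader H2-DMa by 1.97 (SE 0.26, adjusted p = 7.9e-04). 7 of 15 chemokine genes rose (10 adjusted over the list alone, adjusted p = 3.4e-14). Ccl7 was higher by 3.29 (SE 0.37, adjusted p = 2.8e-04) and Cxcl10 by 2.13 (SE 0.24, adjusted p = 2.7e-04). 3 of 9 complement genes rose (4 adjusted over the list alone, adjusted p = 1.5e-06, adjusted p = 0.050 with an estimated correlation). Factor B, Cfb, was higher by at least 2.94-fold (adjusted p = 0.0034). 5 of 17 macrophage and monocyte genes rose (7 adjusted over the list alone, adjusted p = 9.8e-10). 5 of 16 checkpoint and immune suppression genes rose (7 adjusted over the list alone, adjusted p = 2.6e-07). 3 of 9 immediate early genes rose (5 adjusted over the list alone, adjusted p = 7.8e-06). 3 of 19 type I interferon response genes rose (4 adjusted over the list alone, adjusted p = 1.6e-06, adjusted p = 0.061 with an estimated correlation). 1 of 7 dendritic cell genes rose (2 adjusted over the list alone, adjusted p = 0.017, adjusted p = 0.12 with an estimated correlation). The B and plasma cell list was called with no member passing (adjusted p = 0.0046, adjusted p = 0.14 with an estimated correlation, median 0.65). In the neuron list none of 14 neuron genes passed the test (median -0.02, adjusted p = 0.94).

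Choroid plexus genes were lower in WT hosts at day 7, where 5 of 8 choroid plexus genes fell (7 adjusted over the list alone, adjusted p = 1.7e-09, adjusted p = 0.061 with an estimated correlation). Sostdc1, a secreted antagonist of bone morphogenetic proteins, was lower by at least 9.31-fold (adjusted p = 0.0012), and the folate receptor Folr1 by at least 7.02-fold (adjusted p = 0.0080). Kcne2, a potassium channel subunit, had a log2 fold change of -3.40 (SE 0.60, adjusted p = 0.0068), with its probe detected on 1 of the 2 WT arrays. Without Pfp/Rag2 -/- replicate 1, the pool with the most choroid plexus signal, Sostdc1 stayed called (adjusted p = 0.0229), while Kcne2 (adjusted p = 0.107) and Folr1 (adjusted p = 0.103) did not, nor did they without WT replicate 1 (adjusted p = 0.0935 and 0.0923). The defensin gene Defb11 was lower by at least 5.44-fold (adjusted p = 1.5e-05). In all, limma called 346 genes higher and 157 lower of 13726 tested at day 7. That count fell to 125 without WT replicate 1, 271 without WT replicate 2 and 143 without Pfp/Rag2 -/- replicate 1, and rose to 1255 without Pfp/Rag2 -/- replicate 2. It was 63 with only the 4 arrays compared and 287 with only the 14 tumour arrays in the fit, and on the unscaled series values 259 genes were higher and 91 lower.

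At day 14 (2 pools per host), Arg1, an arginine-degrading enzyme made by some macrophages, was higher in WT hosts by at least 28.9-fold (adjusted p = 2.3e-04). The immunoglobulin light chain gene Igkc was higher by 5.18 (SE 0.61, adjusted p = 1.0e-04), Cxcl9 by 5.67 (SE 0.33, adjusted p = 5.6e-07) and Spint1 by 4.97 (SE 0.44, adjusted p = 1.1e-05), each detected on 1 of the 2 Pfp/Rag2 -/- arrays. H2-Eb1, a chain of MHC class II, was higher by 4.24 (SE 0.37, adjusted p = 1.1e-05). 10 of 10 MHC class II genes rose (10 adjusted over the list alone, adjusted p = 9.5e-18). Ciita was higher by at least 12.4-fold (adjusted p = 6.2e-07). 15 of 17 macrophage and monocyte genes rose (15 adjusted over the list alone, adjusted p = 6.7e-16). The Fc receptor Fcgr4 was higher by 3.03 (SE 0.27, adjusted p = 1.1e-05). 11 of 15 T cell genes rose (12 adjusted over the list alone, adjusted p = 4.4e-16). Cd3e was higher by at least 6.93-fold (adjusted p = 1.4e-06). 3 of 5 B and plasma cell genes rose (4 adjusted over the list alone, adjusted p = 2.3e-05). 7 of 9 NK and cytotoxic effector genes rose (7 adjusted over the list alone, adjusted p = 2.8e-08, adjusted p = 0.072 with an estimated correlation). The receptor Klrk1 was higher by at least 2.22-fold (adjusted p = 4.6e-05). 13 of 16 interferon-gamma response genes rose (14 adjusted over the list alone, adjusted p = 2.3e-17). Cd274 was higher by 2.79 (SE 0.15, adjusted p = 3.5e-07). 8 of 9 complement genes rose (9 adjusted over the list alone, adjusted p = 1.2e-10). The C1 inhibitor Serping1 was higher by 3.63 (SE 0.29, adjusted p = 6.9e-06). 11 of 15 chemokine genes rose (13 adjusted over the list alone, adjusted p = 3.0e-14). Cxcl16 was higher by 2.49 (SE 0.17, adjusted p = 2.1e-06).

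Antigen presentation through MHC class I was higher in WT hosts at day 14 too, where 14 of 16 MHC class I genes rose (14 adjusted over the list alone, adjusted p = 1.2e-13). 10 of 16 checkpoint and immune suppression genes rose (12, and 1 lower, adjusted over the list alone, adjusted p = 5.2e-09). 8 of 15 microglia genes rose (9 adjusted over the list alone, adjusted p = 2.7e-08, adjusted p = 0.11 with an estimated correlation). The complement subunit C1qa was higher by 1.92 (SE 0.24, adjusted p = 1.3e-04). 3 of 7 dendritic cell genes rose (4, and 1 lower, adjusted over the list alone, adjusted p = 0.024, adjusted p = 0.14 with an estimated correlation). 1 of 5 neutrophil genes rose (1 adjusted over the list alone, adjusted p = 0.012, adjusted p = 0.10 with an estimated correlation). The iron carrier Lcn2 was higher by 4.75 (SE 0.56, adjusted p = 1.0e-04). 4 of 10 oligodendrocyte genes rose (7, and 1 lower, adjusted over the list alone, adjusted p = 0.0025, adjusted p = 0.23 with an estimated correlation). 2 of 12 astrocyte genes rose (4 adjusted over the list alone, adjusted p = 0.0014, adjusted p = 0.33 with an estimated correlation). Neuron signals averaged 14.1% in WT and 9.77% in Pfp/Rag2 -/- pools. The myelin gene Mag, at 2.16 (SE 0.48, adjusted p = 0.0094), was no longer called without WT replicate 1 (adjusted p = 0.111) or Pfp/Rag2 -/- replicate 2 (adjusted p = 0.116). The choroid plexus list had a median of 1.26 with no member passing (adjusted p = 0.038, adjusted p = 0.47 with an estimated correlation), and it was not called under cyclic loess scaling (adjusted p = 0.10) or without background correction (adjusted p = 0.057).

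Lower in WT hosts at day 14 were the keratin Krt8 at -3.10 (SE 0.50, adjusted p = 0.0011), the transcription factors Irx6 by at least 3.00-fold (adjusted p = 8.4e-06) and Osr2 at -2.05 (SE 0.18, adjusted p = 1.1e-05), and Dmrta1 by at least 3.44-fold (adjusted p = 0.0012). The collagens Col6a1 at -1.22 (SE 0.12, adjusted p = 1.9e-05) and Col1a1 at -1.16 (SE 0.22, adjusted p = 0.0038) were lower while fibronectin, Fn1, was higher by 1.69 (SE 0.39, adjusted p = 0.011), and for the whole list 2 of 18 extracellular matrix genes rose and 4 fell (5 and 5 adjusted over the list alone, adjusted p = 0.72). The proteoglycan Cspg4 was lower at -1.08 (SE 0.18, adjusted p = 0.0012). 1 of 19 type I interferon response genes rose and 4 fell (2 and 9 adjusted over the list alone, adjusted p = 0.012, adjusted p = 0.30 with an estimated correlation). The antiviral gene Oas2 changed by -1.52 (SE 0.31, adjusted p = 0.0051), a call that ended without Pfp/Rag2 -/- replicate 2 (adjusted p = 0.0632). 1 of 23 cell cycle genes fell (0 adjusted over the list alone, adjusted p = 0.040, adjusted p = 0.65 with an estimated correlation). Of 13726 genes, 993 were higher and 903 lower at day 14, a split that was 1292 and 552 under cyclic loess scaling and 819 and 506 on the unscaled series values. The count of 1896 fell to 983 without WT replicate 1, to 913 without Pfp/Rag2 -/- replicate 2 and to 178 with only the 4 arrays compared, a fit in which Arg1 (adjusted p = 0.0763), Krt8 (adjusted p = 0.109), Lcn2 (adjusted p = 0.0517) and C1qa (adjusted p = 0.113) no longer passed.

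At the symptomatic stage (3 pools per host), Arg1 was higher in WT hosts by at least 33.8-fold (adjusted p = 2.8e-05) and Cxcl9 by at least 29.4-fold (adjusted p = 7.7e-08). H2-M2, a class I-like MHC gene, was higher by at least 12.2-fold (adjusted p = 4.6e-08), and Cd74, the invariant chain of MHC class II, by 3.95 (SE 0.32, adjusted p = 3.9e-06). Mmp13, a collagenase, was higher by 4.28 (SE 0.44, adjusted p = 2.4e-05). 10 of 10 MHC class II genes rose (10 adjusted over the list alone, adjusted p = 2.6e-17). Ciita was higher by at least 9.97-fold (adjusted p = 2.4e-08). 15 of 16 interferon-gamma response genes rose (15 adjusted over the list alone, adjusted p = 8.6e-19). Gbp2 was higher by 2.29 (SE 0.10, adjusted p = 3.1e-08). 14 of 16 MHC class I genes rose (16 adjusted over the list alone, adjusted p = 7.8e-17). Psmb9 was higher by 2.15 (SE 0.14, adjusted p = 7.9e-07). 15 of 17 macrophage and monocyte genes rose (16 adjusted over the list alone, adjusted p = 9.2e-14). Fcgr4 was higher by 2.91 (SE 0.22, adjusted p = 2.6e-06). 10 of 15 T cell genes rose (12 adjusted over the list alone, adjusted p = 2.3e-09). Cd3d was higher by at least 3.75-fold (adjusted p = 5.3e-08). 6 of 9 NK and cytotoxic effector genes rose (6 adjusted over the list alone, adjusted p = 2.3e-06, adjusted p = 0.13 with an estimated correlation). 3 of 5 B and plasma cell genes rose (3 adjusted over the list alone, adjusted p = 0.0028, adjusted p = 0.15 with an estimated correlation). Igkc was higher by at least 6.09-fold (adjusted p = 6.0e-04). 11 of 15 chemokine genes rose (12, and 1 lower, adjusted over the list alone, adjusted p = 1.5e-09). 9 of 9 complement genes rose (9 adjusted over the list alone, adjusted p = 7.3e-10). C3 was higher by 2.77 (SE 0.33, adjusted p = 9.3e-05).

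Other lists rose in smaller part in symptomatic WT hosts. 7 of 16 checkpoint and immune suppression genes rose (7 adjusted over the list alone, adjusted p = 7.5e-05, adjusted p = 0.12 with an estimated correlation). 7 of 15 microglia genes rose (9, and 1 lower, adjusted over the list alone, adjusted p = 6.7e-05, adjusted p = 0.23 with an estimated correlation). Olfml3 was higher by 1.76 (SE 0.14, adjusted p = 3.0e-06). 4 of 14 hypoxia and glycolysis genes rose (5 adjusted over the list alone, adjusted p = 0.0022). The glycolytic enzyme Aldoa was higher by 0.57 (SE 0.12, adjusted p = 0.0045). 1 of 23 cell cycle genes rose (0 adjusted over the list alone, adjusted p = 0.020, adjusted p = 0.63 with an estimated correlation) and 1 of 14 cholesterol synthesis genes rose (1 adjusted over the list alone, adjusted p = 0.0082, adjusted p = 0.49 with an estimated correlation).

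Lower in symptomatic WT hosts were Ramp1, a receptor co-factor, at -2.74 (SE 0.24, adjusted p = 7.1e-06), the acetylcholine receptor subunit Chrna4 at -2.01 (SE 0.33, adjusted p = 0.0011) and Krt8 at -2.01 (SE 0.41, adjusted p = 0.0043). Comp, a cartilage matrix protein, was lower by at least 4.77-fold (adjusted p = 8.9e-04) and the protocadherin Pcdhb12 by at least 2.38-fold (adjusted p = 9.3e-08). Col6a1 at -1.21 (SE 0.10, adjusted p = 3.0e-06) and Col1a1 at -1.31 (SE 0.18, adjusted p = 3.0e-04) were lower while Fn1 was higher by 1.68 (SE 0.32, adjusted p = 0.0028), and 2 of 18 extracellular matrix genes rose and 4 fell (2 and 4 adjusted over the list alone, adjusted p = 0.97). 1 of 19 type I interferon response genes rose and 8 fell (1 and 10 adjusted over the list alone, adjusted p = 0.0067, adjusted p = 0.26 with an estimated correlation). The transcription factor Irf7 changed by -0.96 (SE 0.14, adjusted p = 4.7e-04) and Oas2 by -1.52 (SE 0.25, adjusted p = 0.0010). 4 of 9 immediate early genes fell (4 adjusted over the list alone, adjusted p = 0.042, adjusted p = 0.23 with an estimated correlation). Egr1 changed by -0.96 (SE 0.17, adjusted p = 0.0015), and the immediate early list was not called under cyclic loess scaling (adjusted p = 0.056). 1 of 11 glioma stem and progenitor genes fell (3 adjusted over the list alone, adjusted p = 0.033, adjusted p = 0.23 with an estimated correlation). Neither this list (adjusted p = 0.059) nor that of immediate early genes (adjusted p = 0.055) was called with the neuron level as a covariate. Cspg4 changed by -0.90 (SE 0.14, adjusted p = 8.7e-04). 3 of 10 oligodendrocyte genes fell (5 adjusted over the list alone, adjusted p = 0.0028, adjusted p = 0.23 with an estimated correlation). Opalin of myelin changed by -1.85 (SE 0.42, adjusted p = 0.0089), and the neuron list, where none of 14 passed, had a median of -0.85 (adjusted p = 0.025, adjusted p = 0.57 with an estimated correlation). Neuron signals averaged 2.98% in WT and 7.07% in Pfp/Rag2 -/- pools. In all 1287 genes were higher and 1106 lower, a count of 2393 that was 1566 without WT replicate 3 and 1578 without Pfp/Rag2 -/- replicate 2, numbered as in the titles. On the unscaled series values 1265 were higher and 351 lower. With the oligodendrocyte level as a covariate 552 were higher and 464 lower, and Chrna4 (adjusted p = 0.085), Egr1 (adjusted p = 0.099), Opalin (adjusted p = 0.33) and Irf7 (adjusted p = 0.064) were not called.

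**Figure D2:**
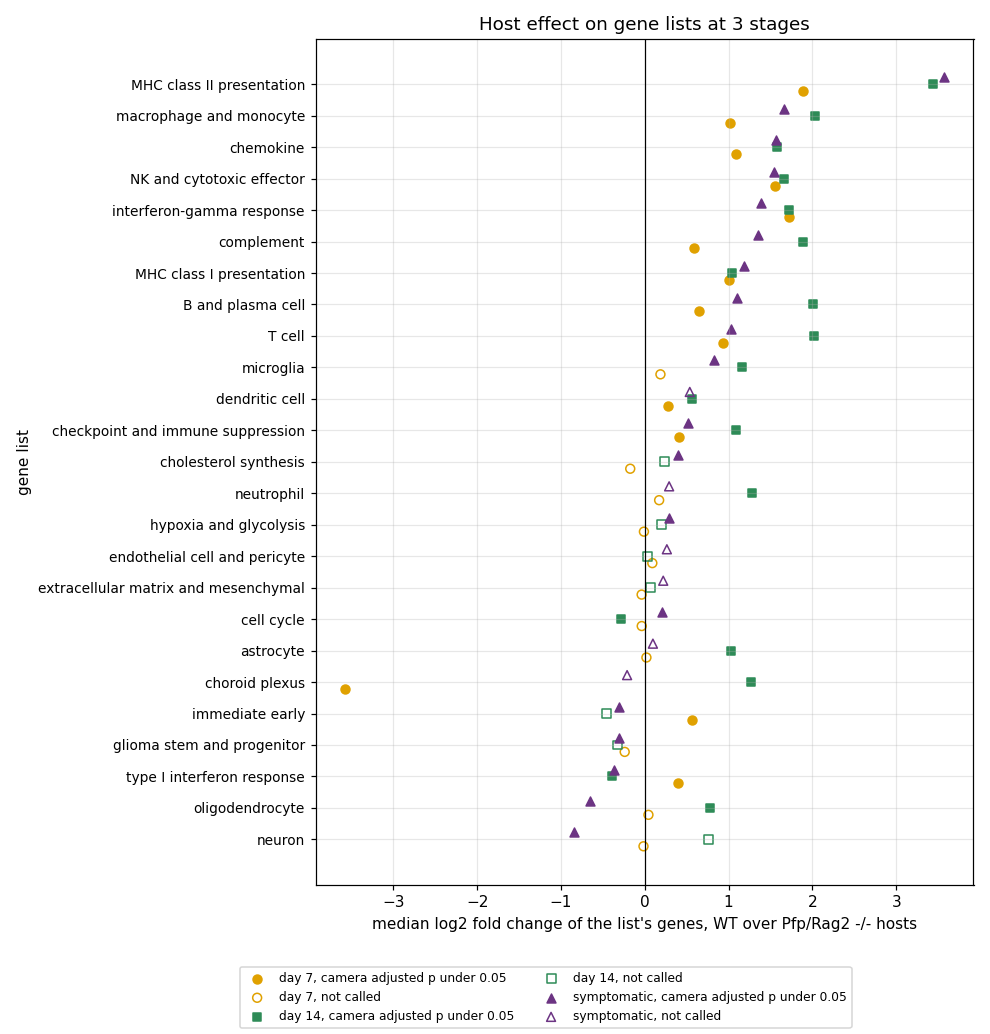
Median log2 fold change, WT minus Pfp/Rag2 -/- hosts, of gene lists at day 7 (2 against 2 arrays), day 14 (2 against 2) and the symptomatic stage (3 against 3). Filled points have a camera adjusted p under 0.05. The MHC class II list stood at 1.89, 3.44 and 3.57 and the choroid plexus list at -3.57, 1.26 and -0.21, the day 14 call of the latter ending under cyclic loess scaling.

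As a mean over the 3 stages, with equal weight, Cxcl9 was higher in WT hosts by at least 33.7-fold (adjusted p = 7.2e-10), Arg1 by at least 19.5-fold (adjusted p = 2.2e-06) and Ubd by at least 16.4-fold (adjusted p = 4.0e-10). 16 of 16 interferon-gamma response genes rose (16 adjusted over the list alone, adjusted p = 7.1e-25), 17 of 17 macrophage and monocyte genes rose (17 adjusted over the list alone, adjusted p = 2.7e-18) and 10 of 10 MHC class II genes rose (10 adjusted over the list alone, adjusted p = 1.1e-19). 9 of 9 NK and cytotoxic effector genes rose (9 adjusted over the list alone, adjusted p = 9.0e-11), 9 of 9 complement genes rose (9 adjusted over the list alone, adjusted p = 2.7e-12) and 5 of 5 B and plasma cell genes rose (5 adjusted over the list alone, adjusted p = 1.6e-05). 13 of 15 T cell genes rose (13 adjusted over the list alone, adjusted p = 3.6e-16), 15 of 16 MHC class I genes rose (15 adjusted over the list alone, adjusted p = 1.1e-19) and 13 of 15 chemokine genes rose (14 adjusted over the list alone, adjusted p = 3.5e-16). 12 of 16 checkpoint and immune suppression genes rose (12, and 1 lower, adjusted over the list alone, adjusted p = 2.6e-09). 8 of 15 microglia genes rose (10 adjusted over the list alone, adjusted p = 2.7e-07, adjusted p = 0.12 with an estimated correlation), 2 of 5 neutrophil genes rose (2 adjusted over the list alone, adjusted p = 0.024, adjusted p = 0.12 with an estimated correlation) and 2 of 14 hypoxia and glycolysis genes rose (2 adjusted over the list alone, adjusted p = 0.0082). 2 of 12 astrocyte genes rose (2 adjusted over the list alone, adjusted p = 0.032, adjusted p = 0.61 with an estimated correlation), a list not called under cyclic loess scaling (adjusted p = 0.060). 4 of 7 dendritic cell genes rose and 1 fell (5 and 1 adjusted over the list alone, adjusted p = 0.019, adjusted p = 0.12 with an estimated correlation). Lower were Krt8 at -2.08 (SE 0.27, adjusted p = 9.8e-05), Chrna4 at -1.89 (SE 0.22, adjusted p = 3.9e-05) and Osr2 at -1.51 (SE 0.10, adjusted p = 2.1e-07). 4 of 11 glioma stem and progenitor genes fell (5 adjusted over the list alone, adjusted p = 0.032, adjusted p = 0.20 with an estimated correlation) and 2 of 8 choroid plexus genes fell (3 adjusted over the list alone, adjusted p = 0.049, adjusted p = 0.61 with an estimated correlation). The lists of type I interferon response, endothelial cells, cell cycle, extracellular matrix, neurons, oligodendrocytes, cholesterol synthesis and immediate early genes were not called (adjusted p = 0.11 for cholesterol synthesis and 0.22 to 0.91 for the others). Hba-a1, the red blood cell gene measured, was higher by 1.12 (SE 0.26, adjusted p = 0.0076). At day 7 it was not called (-0.25, SE 0.48, adjusted p = 0.90), at day 14 it was higher by 2.29 (SE 0.48, adjusted p = 0.0062) and at the symptomatic stage by 1.33 (SE 0.39, adjusted p = 0.031). Of the sex-linked genes Xist was higher by 0.71 (SE 0.17, adjusted p = 0.010) and Ddx3y of the Y chromosome was not called (0.03, SE 0.10, adjusted p = 0.89). By stage, Xist differed by 0.10 (SE 0.32, adjusted p = 0.95), 1.27 (SE 0.32, adjusted p = 0.017) and 0.77 (SE 0.26, adjusted p = 0.058) at day 7, day 14 and the symptomatic stage. Ddx3y differed by 0.05 (SE 0.19, adjusted p = 0.96), -0.53 (SE 0.19, adjusted p = 0.078) and 0.57 (SE 0.15, adjusted p = 0.021). The mean called 1306 genes higher and 1452 lower, which was 1601 and 1106 under cyclic loess scaling. On the unscaled series values 1189 were higher and 524 lower, 1713 in all, and at least 2-fold 432 were higher and 50 lower.

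Of the 346 genes higher in WT hosts at day 7, 255 were also higher at day 14 (25.0 expected if the calls were independent) and 254 at the symptomatic stage (32.4 expected), and of the 993 higher at day 14, 663 were at the symptomatic stage (93.1 expected). Of the 157 lower in WT hosts at day 7, only 21 were also lower at day 14 (10.3 expected) and 25 at the symptomatic stage (12.7 expected), and of the 903 lower at day 14, 343 were at the symptomatic stage (72.8 expected). Across all 3 stages 235 genes were higher and 15 lower in WT hosts.

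The difference of the host effects, symptomatic minus day 7, was tested directly in the fit of all 18 arrays. 4 of 10 MHC class II genes were called above 0 (8 adjusted over the list alone, adjusted p = 5.8e-08, adjusted p = 0.20 with an estimated correlation). H2-Eb1 had a difference of 2.51 (SE 0.48, adjusted p = 0.022). 4 of 19 type I interferon response genes were called below 0 (11 adjusted over the list alone, adjusted p = 1.3e-08, adjusted p = 0.12 with an estimated correlation). Irf7 of this list had -1.38 (SE 0.22, adjusted p = 0.010). 2 of 9 immediate early genes were called below 0 (8 adjusted over the list alone, adjusted p = 6.5e-07, adjusted p = 0.053 with an estimated correlation), with Egr1 at -1.55 (SE 0.26, adjusted p = 0.013). Ramp1 at -2.89 (SE 0.38, adjusted p = 0.0042) and Zfp365 at -3.17 (SE 0.26, adjusted p = 8.2e-05) also had a lower host effect at the symptomatic stage. None of the 12 list calls held with an estimated correlation. In all 168 genes were called above and 171 below 0. Without WT day 7 replicate 1, H2-Eb1 (adjusted p = 0.118), Irf7 (adjusted p = 0.0521) and Egr1 (adjusted p = 0.0678) were not called and 31 genes in all were, and H2-Eb1 was not called either without WT symptomatic replicate 3 (adjusted p = 0.0566) or Pfp/Rag2 -/- symptomatic replicate 2 (adjusted p = 0.0615). The count of 339 was 175 with only the 10 arrays of those stages in the fit, 176 on the unscaled series values (129 above, 47 below) and 113 without WT day 7 replicate 2, 177 without Pfp/Rag2 -/- day 7 replicate 1, 769 without Pfp/Rag2 -/- day 7 replicate 2, 182 and 121 without WT symptomatic replicates 2 and 3, and 195, 104 and 149 without Pfp/Rag2 -/- symptomatic replicates 1, 2 and 3.

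**Figure D3:**
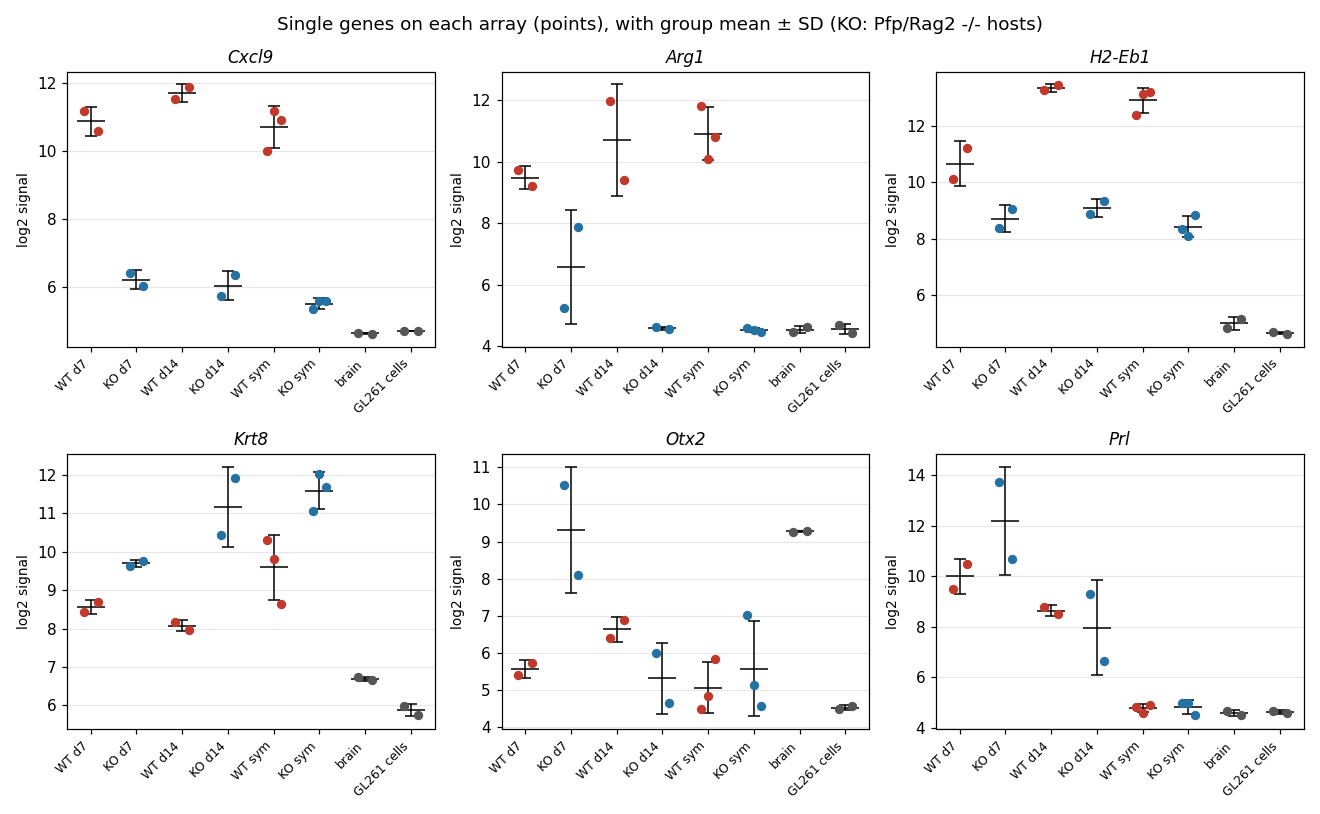
Log2 signal of Cxcl9, Arg1, H2-Eb1, Krt8, Otx2 and Prl on each array (points), by group, with group means (bars). Cxcl9 averaged 10.88, 11.70 and 10.71 in WT hosts at day 7, day 14 and the symptomatic stage and 4.63 in healthy brain, and Prl 10.00 and 12.18 at day 7 in WT and Pfp/Rag2 -/- hosts and 4.79 in symptomatic WT hosts.

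The stage comparison asks how tumours at the symptomatic stage (3 pools) differ from those at day 7 (2 pools) within one host type. In WT hosts, genes of neurons, oligodendrocytes and astrocytes fell, where the neuron signal went from 32.4% to 2.98% of healthy brain. 13 of 14 neuron genes fell (13 adjusted over the list alone, adjusted p = 4.4e-06, adjusted p = 0.40 with an estimated correlation). Nrgn changed by -4.52 (SE 0.60, adjusted p = 1.4e-04), its probe detected on 2 of the 3 symptomatic arrays. 1 of 10 oligodendrocyte genes rose and 9 fell (1 and 9 adjusted over the list alone, adjusted p = 1.6e-04, adjusted p = 0.39 with an estimated correlation). The myelin gene Mag changed by -3.29 (SE 0.44, adjusted p = 1.4e-04). 11 of 12 astrocyte genes fell (11 adjusted over the list alone, adjusted p = 3.9e-05, adjusted p = 0.40 with an estimated correlation). The glutamate transporter Slc1a2 changed by -3.37 (SE 0.54, adjusted p = 3.5e-04). Prl was lower by at least 17.5-fold (adjusted p = 2.2e-04). 23 of 23 cell cycle genes rose (23 adjusted over the list alone, adjusted p = 4.4e-06, adjusted p = 0.45 with an estimated correlation). The replication helicase subunit Mcm2 changed by 1.20 (SE 0.17, adjusted p = 2.1e-04) and Mcm6 by 0.98 (SE 0.15, adjusted p = 2.5e-04). 8 of 10 MHC class II genes rose (8 adjusted over the list alone, adjusted p = 0.0033, adjusted p = 0.45 with an estimated correlation). H2-DMb1 changed by 1.66 (SE 0.18, adjusted p = 4.9e-05), and H2-M2 was higher by at least 14.5-fold (adjusted p = 1.5e-06). 10 of 16 MHC class I genes rose (10 adjusted over the list alone, adjusted p = 0.014, adjusted p = 0.45 with an estimated correlation). 11 of 14 hypoxia and glycolysis genes rose and 1 fell (11 and 1 adjusted over the list alone, adjusted p = 0.028, adjusted p = 0.38 with an estimated correlation). Pdk1 changed by 0.85 (SE 0.12, adjusted p = 2.3e-04). 10 of 14 cholesterol synthesis genes rose (10 adjusted over the list alone, adjusted p = 0.0077, adjusted p = 0.62 with an estimated correlation). Dhcr7 changed by 1.41 (SE 0.24, adjusted p = 5.8e-04).

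Interferon genes fell with stage in WT hosts. 12 of 19 type I interferon response genes fell (12 adjusted over the list alone, adjusted p = 5.7e-05, adjusted p = 0.38 with an estimated correlation). Ifit3 changed by -1.52 (SE 0.13, adjusted p = 1.8e-05) and Irf7 by -1.47 (SE 0.16, adjusted p = 4.9e-05). 6 of 16 interferon-gamma response genes fell (6 adjusted over the list alone, adjusted p = 0.0044, adjusted p = 0.40 with an estimated correlation). Cxcl10 changed by -2.14 (SE 0.22, adjusted p = 4.6e-05) and Ido1 by -3.76 (SE 0.42, adjusted p = 6.3e-05), a gene whose log2 signal in healthy brain was 11.31 (SD 0.04, n = 2). 6 of 15 chemokine genes fell (6 adjusted over the list alone, adjusted p = 0.0065, adjusted p = 0.38 with an estimated correlation). Ccl2 was lower by at least 3.87-fold (adjusted p = 1.9e-05). 2 of 15 microglia genes rose and 8 fell (2 and 8 adjusted over the list alone, adjusted p = 0.0078, adjusted p = 0.54 with an estimated correlation). The median of the microglia list turned to 0.25 with the neuron level as a covariate (adjusted p = 0.52), where the MHC class I and astrocyte lists were not called either (adjusted p = 0.43 and 0.52). Fcrls changed by -2.47 (SE 0.27, adjusted p = 5.3e-05). The 13 remaining lists were not called, apart from immediate early genes under cyclic loess (adjusted p = 0.039) and median scaling (adjusted p = 0.036). In all 4272 genes rose and 2961 fell, against 2388 and 3915 under cyclic loess and 1808 and 4155 under median scaling, which moved the median of all genes from 0.16 to -0.06 and -0.10. With the neuron level as a covariate 55 genes were called, of those named here H2-M2 and Ccl2, the unscaled series values called 270 higher and 4526 lower (4796 in all, median of all genes -0.58), and the count was 4609 without WT day 7 replicate 1.

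In Pfp/Rag2 -/- hosts the same comparison (3 against 2 pools) had the neuron signal at 7.07% against 34.7% of healthy brain. Prl was lower at the symptomatic stage by at least 81.8-fold (adjusted p = 1.0e-04) and Gh by at least 26.6-fold (adjusted p = 0.0013). The day 7 pools differed, with log2 signals of 13.70 and 10.67 for Prl and 12.90 and 8.23 for Gh, so both limits rest largely on replicate 1, without which both genes stayed called (adjusted p = 0.0015 and 0.0076). Gh was not called with the neuron level as a covariate (adjusted p = 0.14). 7 of 8 choroid plexus genes fell (7 adjusted over the list alone, adjusted p = 1.7e-04, adjusted p = 0.43 with an estimated correlation). Sostdc1 was lower by at least 7.82-fold (adjusted p = 1.6e-04). 11 of 12 astrocyte genes fell (11 adjusted over the list alone, adjusted p = 1.8e-05, adjusted p = 0.43 with an estimated correlation). The gap junction gene Gja1 changed by -1.44 (SE 0.20, adjusted p = 3.9e-04). 12 of 14 neuron genes fell (13 adjusted over the list alone, adjusted p = 9.7e-05, adjusted p = 0.47 with an estimated correlation). Stmn2 changed by -3.29 (SE 0.77, adjusted p = 0.0042), a call lost without Pfp/Rag2 -/- day 7 replicate 1 (adjusted p = 0.0663). 1 of 10 oligodendrocyte genes rose and 6 fell (1 and 7 adjusted over the list alone, adjusted p = 0.0064, adjusted p = 0.43 with an estimated correlation), a list not called with the neuron level as a covariate (adjusted p = 0.11). Ugt8a of myelin lipid synthesis changed by -1.44 (SE 0.24, adjusted p = 7.5e-04). 13 of 15 microglia genes fell (13 adjusted over the list alone, adjusted p = 9.8e-06, adjusted p = 0.43 with an estimated correlation). Trem2 changed by -1.71 (SE 0.27, adjusted p = 5.9e-04). 1 of 17 macrophage and monocyte genes rose and 9 fell (1 and 9 adjusted over the list alone, adjusted p = 0.0018, adjusted p = 0.43 with an estimated correlation). The growth factor receptor Csf1r changed by -1.37 (SE 0.22, adjusted p = 6.7e-04). 7 of 16 interferon-gamma response genes fell (7 adjusted over the list alone, adjusted p = 0.0027, adjusted p = 0.43 with an estimated correlation). Gbp2 changed by -1.15 (SE 0.12, adjusted p = 1.0e-04). 10 of 15 chemokine genes fell (11, and 1 higher, adjusted over the list alone, adjusted p = 3.6e-04, adjusted p = 0.32 with an estimated correlation). Ccl4 changed by -1.80 (SE 0.20, adjusted p = 1.5e-04).

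Cell cycle genes rose with stage in Pfp/Rag2 -/- hosts, where 20 of 23 cell cycle genes rose (21 adjusted over the list alone, adjusted p = 9.7e-05, adjusted p = 0.53 with an estimated correlation). Tk1 changed by 0.94 (SE 0.19, adjusted p = 0.0019), which the unscaled series values did not call (adjusted p = 0.217). 4 of 9 immediate early genes rose (5 adjusted over the list alone, adjusted p = 0.042, adjusted p = 0.43 with an estimated correlation). Fos changed by 0.77 (SE 0.11, adjusted p = 4.5e-04), which the unscaled series values did not call (adjusted p = 0.349). This list was not called under cyclic loess (adjusted p = 0.071) or median scaling (adjusted p = 0.074). The transcription factors Irx6 by at least 3.81-fold (adjusted p = 1.7e-05) and Gata2 at 2.21 (SE 0.21, adjusted p = 9.0e-05) were higher. In all 3737 genes rose and 3006 fell, against 2083 and 3827 under cyclic loess and 1464 and 4139 under median scaling, which moved the median of all genes from 0.14 to -0.05 and -0.11. On the unscaled series values 177 rose and 5346 fell, with a median of all genes of -0.77. With the neuron level as a covariate 214 genes were called, among them Prl, Sostdc1, Gja1, Gbp2, Ccl4, Irx6 and Gata2, and without Pfp/Rag2 -/- day 7 replicate 1 the count was 3323.

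Symptomatic tumours of both hosts (6 pools) were compared with GL261 cells in culture (2 arrays), which asks what the tumours hold beyond the cultured line. H19, an imprinted non-coding RNA, was higher in tumours by at least 366-fold (adjusted p = 4.6e-11), the leukocyte membrane protein Laptm5 by at least 56.8-fold (adjusted p = 4.2e-11) and Cd74 by at least 40.5-fold (adjusted p = 3.0e-09). 9 of 9 complement genes rose (9 adjusted over the list alone, adjusted p = 2.2e-10). C1qb was higher by at least 30.7-fold (adjusted p = 1.2e-10). 14 of 15 microglia genes rose (14 adjusted over the list alone, adjusted p = 1.7e-11, adjusted p = 0.080 with an estimated correlation) and 15 of 17 macrophage and monocyte genes rose (15 adjusted over the list alone, adjusted p = 2.6e-12), the latter with the lysozyme Lyz1 at 5.24 (SE 0.21, adjusted p = 6.4e-10). 13 of 13 endothelial and pericyte genes rose (13 adjusted over the list alone, adjusted p = 5.6e-10, adjusted p = 0.050 with an estimated correlation). The tight junction gene Cldn5 was higher by at least 15.1-fold (adjusted p = 2.0e-10). 10 of 10 MHC class II genes rose (10 adjusted over the list alone, adjusted p = 8.7e-10, adjusted p = 0.080 with an estimated correlation). H2-Ab1 was higher by at least 49.2-fold (adjusted p = 3.2e-09). 15 of 16 MHC class I genes rose and 1 fell (15 and 1 adjusted over the list alone, adjusted p = 3.4e-10, adjusted p = 0.050 with an estimated correlation). H2-T23 changed by 2.66 (SE 0.16, adjusted p = 2.4e-08). 13 of 16 interferon-gamma response genes rose and 1 fell (13 and 1 adjusted over the list alone, adjusted p = 9.6e-07, adjusted p = 0.081 with an estimated correlation) and 10 of 16 checkpoint and immune suppression genes rose (11 adjusted over the list alone, adjusted p = 9.7e-05, adjusted p = 0.11 with an estimated correlation). Cd274 changed by 2.22 (SE 0.13, adjusted p = 1.7e-08). 10 of 15 chemokine genes rose and 1 fell (11 and 1 adjusted over the list alone, adjusted p = 1.5e-05). Cxcl16 was higher by at least 8.47-fold (adjusted p = 1.9e-10). 8 of 9 immediate early genes rose and 1 fell (8 and 1 adjusted over the list alone, adjusted p = 0.0021, adjusted p = 0.083 with an estimated correlation). Egr1 changed by 1.36 (SE 0.17, adjusted p = 2.4e-05).

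Of the lymphocyte lists, that of T cells had a mean log2 signal of 6.64 (SD 0.26, n = 3) in symptomatic WT hosts, 5.51 (SD 0.06, n = 3) in Pfp/Rag2 -/- hosts and 5.56 (SD 0.05, n = 2) in cultured cells, so the mean rose in the WT pools alone. In the same groups the NK list had means of 6.97, 5.62 and 5.08 and the B cell list 7.02, 5.64 and 4.88. Over the tumours of both hosts 8 of 15 T cell genes rose and 1 fell (8 and 1 adjusted over the list alone, adjusted p = 0.034, adjusted p = 0.36 with an estimated correlation), 6 of 9 NK and cytotoxic effector genes rose (7 adjusted over the list alone, adjusted p = 0.0021, adjusted p = 0.30 with an estimated correlation) and 4 of 5 B and plasma cell genes rose (4 adjusted over the list alone, adjusted p = 0.026, adjusted p = 0.28 with an estimated correlation), calls that ended under median scaling (adjusted p = 0.54, 0.072 and 0.19), those of T and B cells under cyclic loess too (adjusted p = 0.15 and 0.074) and that of T cells without background correction (adjusted p = 0.064). Cd72 of B cells was higher by at least 5.24-fold (adjusted p = 2.0e-07) and Cd3g by at least 1.77-fold (adjusted p = 1.3e-06). 8 of 14 neuron genes rose (8 adjusted over the list alone, adjusted p = 0.0028, adjusted p = 0.48 with an estimated correlation), not called under median scaling (adjusted p = 0.096). Lower in tumours were the growth factor receptor Fgfr3 by at least 14.7-fold (adjusted p = 6.5e-11), Entpd2 at -4.51 (SE 0.31, adjusted p = 1.2e-07) and the neurotrophin receptor Ngfr at -3.82 (SE 0.29, adjusted p = 3.4e-07). 7 of 23 cell cycle genes fell (7 adjusted over the list alone, adjusted p = 0.0063, adjusted p = 0.54 with an estimated correlation). Ube2c changed by -1.23 (SE 0.20, adjusted p = 3.4e-04), its probe detected on 5 of 6 tumour arrays. 1 of 14 cholesterol synthesis genes rose and 6 fell (1 and 6 adjusted over the list alone, adjusted p = 0.027, adjusted p = 0.54 with an estimated correlation). Col6a1 was lower at -2.56 (SE 0.10, adjusted p = 3.5e-10). In all 2748 genes were higher and 2533 lower, against 3997 and 1192 under median scaling and 5230 and 340 on the unscaled series values, which moved the median of all genes from 0.00 to 0.17 and 0.60. The count of 5281 was 3175 and 3404 without replicate 1 or replicate 2 of the cultured cells.

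Against healthy brain (2 arrays), symptomatic tumours (6 pools) held more H19, by at least 500-fold (adjusted p = 2.4e-12), more of the transcription factor Osr2, by at least 86.7-fold (adjusted p = 3.9e-13), and more Gpnmb, a glycoprotein of melanocytes and macrophages, at 7.29 (SE 0.13, adjusted p = 2.0e-13). 23 of 23 cell cycle genes rose (23 adjusted over the list alone, adjusted p = 3.0e-10, adjusted p = 0.33 with an estimated correlation). Cdk1 was higher by at least 52.4-fold (adjusted p = 3.1e-12) and Cdc20 by 6.12 (SE 0.15, adjusted p = 2.4e-12). 19 of 19 type I interferon response genes rose (19 adjusted over the list alone, adjusted p = 2.1e-07, adjusted p = 0.25 with an estimated correlation). Rsad2 was higher by at least 62.9-fold (adjusted p = 2.2e-12). 16 of 16 MHC class I genes rose (16 adjusted over the list alone, adjusted p = 1.2e-07, adjusted p = 0.25 with an estimated correlation). Psmb9 changed by 5.49 (SE 0.14, adjusted p = 2.8e-12). 15 of 16 interferon-gamma response genes rose and 1 fell (15 and 1 adjusted over the list alone, adjusted p = 3.9e-06, adjusted p = 0.25 with an estimated correlation). Gbp3 changed by 5.21 (SE 0.09, adjusted p = 2.0e-13), and the member that fell was Ido1 at -4.45 (SE 0.38, adjusted p = 1.8e-07). 10 of 10 MHC class II genes rose (10 adjusted over the list alone, adjusted p = 5.6e-04, adjusted p = 0.33 with an estimated correlation). Cd74 was higher by at least 55.2-fold (adjusted p = 1.7e-09). 9 of 9 complement genes rose (9 adjusted over the list alone, adjusted p = 0.0042, adjusted p = 0.33 with an estimated correlation). C2 changed by 5.64 (SE 0.15, adjusted p = 3.2e-12), and 10 of 15 chemokine genes rose and 1 fell (10 and 1 adjusted over the list alone, adjusted p = 0.011, adjusted p = 0.28 with an estimated correlation). Cxcl10 was higher by at least 19.9-fold (adjusted p = 4.4e-11). 14 of 17 macrophage and monocyte genes rose (14 adjusted over the list alone, adjusted p = 0.0030, adjusted p = 0.33 with an estimated correlation). Fcgr4 was higher by at least 16.7-fold (adjusted p = 5.9e-10).

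Brain cell genes were lower in symptomatic tumours than in healthy brain. 14 of 14 neuron genes fell (14 adjusted over the list alone, adjusted p = 5.2e-05, adjusted p = 0.35 with an estimated correlation). Nefm was lower by at least 24.5-fold (adjusted p = 1.6e-06) and the vesicular glutamate transporter Slc17a6 by at least 121-fold (adjusted p = 7.5e-05). 1 of 10 oligodendrocyte genes rose and 9 fell (1 and 9 adjusted over the list alone, adjusted p = 0.0016, adjusted p = 0.33 with an estimated correlation). Mog of myelin changed by -3.45 (SE 0.28, adjusted p = 1.1e-07), and the member that rose was the transcription factor Sox10 at 1.86 (SE 0.11, adjusted p = 5.0e-09). 10 of 12 astrocyte genes fell (10 adjusted over the list alone, adjusted p = 0.0029, adjusted p = 0.40 with an estimated correlation). Slc1a2 changed by -4.18 (SE 0.48, adjusted p = 2.9e-06). 8 of 8 choroid plexus genes fell (8 adjusted over the list alone, adjusted p = 0.0086, adjusted p = 0.40 with an estimated correlation). Sostdc1 was lower by at least 9.51-fold (adjusted p = 4.8e-07). The NK list was not called (adjusted p = 0.055) but was under cyclic loess (adjusted p = 0.024). In all 5971 genes were higher and 4802 lower, against 4870 and 5721 under cyclic loess, which moved the median of all genes from 0.17 to -0.06, and the unscaled series values called 6796, 3719 higher and 3077 lower.

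Cultured GL261 cells (2 arrays) differed from healthy brain (2 arrays) in most genes tested. 23 of 23 cell cycle genes rose (23 adjusted over the list alone, adjusted p = 1.3e-10, adjusted p = 0.41 with an estimated correlation). Cdk1 was higher by at least 83.9-fold (adjusted p = 2.2e-11). 18 of 19 type I interferon response genes rose (18 adjusted over the list alone, adjusted p = 9.7e-07, adjusted p = 0.41 with an estimated correlation). Rsad2 was higher by at least 52.8-fold (adjusted p = 3.7e-11) and Usp18 by 5.67 (SE 0.20, adjusted p = 9.0e-11). 15 of 16 MHC class I genes rose (15 adjusted over the list alone, adjusted p = 2.9e-05, adjusted p = 0.41 with an estimated correlation). B2m changed by 2.38 (SE 0.11, adjusted p = 8.4e-10). 12 of 16 interferon-gamma response genes rose and 2 fell (12 and 2 adjusted over the list alone, adjusted p = 0.0014, adjusted p = 0.41 with an estimated correlation). Igtp changed by 4.97 (SE 0.16, adjusted p = 5.3e-11) and Ido1 was lower by at least 33.7-fold (adjusted p = 4.5e-08). The collagen Col2a1 was higher by at least 110-fold (adjusted p = 8.5e-10) and the developmental regulator Tfap2a by at least 51.1-fold (adjusted p = 7.5e-11). 14 of 14 neuron genes fell (14 adjusted over the list alone, adjusted p = 1.4e-05, adjusted p = 0.48 with an estimated correlation). Nrgn was lower by at least 44.8-fold (adjusted p = 4.7e-07) and the synaptic gene Cplx1 by at least 395-fold (adjusted p = 1.2e-07). 1 of 10 oligodendrocyte genes rose and 9 fell (1 and 9 adjusted over the list alone, adjusted p = 0.0013, adjusted p = 0.41 with an estimated correlation). Mag was lower by at least 131-fold (adjusted p = 7.0e-09). 13 of 13 endothelial and pericyte genes fell (13 adjusted over the list alone, adjusted p = 1.1e-05, adjusted p = 0.41 with an estimated correlation). Cldn5 was lower by at least 15.9-fold (adjusted p = 3.5e-10). 12 of 15 microglia genes fell (13 adjusted over the list alone, adjusted p = 2.9e-05, adjusted p = 0.41 with an estimated correlation). C1qb was lower by at least 15.1-fold (adjusted p = 7.4e-10).

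Astrocyte and choroid plexus genes were lower in culture than in brain too. 2 of 12 astrocyte genes rose and 10 fell (2 and 10 adjusted over the list alone, adjusted p = 0.012, adjusted p = 0.63 with an estimated correlation). Slc4a4 was lower by at least 40.3-fold (adjusted p = 3.4e-07) and Fgfr3 higher by 2.65 (SE 0.17, adjusted p = 1.3e-08). 8 of 8 choroid plexus genes fell (8 adjusted over the list alone, adjusted p = 0.0075, adjusted p = 0.60 with an estimated correlation). Otx2 was lower by at least 8.26-fold (adjusted p = 1.1e-04). 7 of 17 macrophage and monocyte genes fell (7 adjusted over the list alone, adjusted p = 0.038, adjusted p = 0.61 with an estimated correlation), a list not called under cyclic loess (adjusted p = 0.13), median scaling (adjusted p = 0.092) or without background correction (adjusted p = 0.10). In all 5793 genes were higher and 4716 lower, against 4362 and 5647 under cyclic loess, which moved the median of all genes from 0.18 to -0.11, and the unscaled series values called 6803, 2766 higher and 4037 lower.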

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

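The tests on the choroid plexus list and on the interferon-gamma and MHC class II lists, and those on the share of tumour cells and on brain tissue for the genes lower in WT hosts, were chosen after the result was seen, while the splits of the arrays were set before their counts were seen.

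The host effect differed between day 7 and the symptomatic stage by a direct test of the difference for 339 genes, 20 of which are given here with symptomatic minus day 7 values from the fit of all 18 arrays. Above 0 were H2-M2 (4.66, adjusted p = 3.3e-05), Sostdc1 (3.46, adjusted p = 0.017), Kcne2 (3.36, adjusted p = 0.042), Msx1 (3.27, adjusted p = 0.048), Defb11 (3.20, adjusted p = 3.6e-04), Gzmd (3.11, adjusted p = 0.042), H2-Eb2 (2.91, adjusted p = 0.010), Apol6 (2.77, adjusted p = 1.3e-04), Esm1 (2.71, adjusted p = 0.038) and Ogn (2.70, adjusted p = 0.022). Below 0 were Zfp365 (-3.17, adjusted p = 8.2e-05), Tesc (-3.04, adjusted p = 0.029), Fam171a1 (-2.96, adjusted p = 0.018), Ramp1 (-2.89, adjusted p = 0.0042), Pcdhb12 (-2.61, adjusted p = 3.3e-05), Ppp1r16b (-2.52, adjusted p = 0.0047), Rem2 (-2.52, adjusted p = 0.022), Drd2 (-2.51, adjusted p = 0.041), Sptb (-2.43, adjusted p = 0.049) and Plppr5 (-2.30, adjusted p = 0.029). These are fitted differences and no folds for H2-M2, Sostdc1, Defb11, Gzmd, H2-Eb2, Apol6 and Ogn, whose probes were at background in groups of both sides, and for Pcdhb12 and Drd2, at background on 1 side. Leaving out single arrays ended calls of the 20 other than H2-M2, Defb11, Apol6, Zfp365, Ramp1, Pcdhb12 and Ppp1r16b, and the count fell as low as 31 without WT day 7 replicate 1.

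For lists the same test gave medians of 3.34 for choroid plexus (adjusted p = 2.6e-05), 1.495 for MHC class II (adjusted p = 5.8e-08), 0.99 for complement (adjusted p = 0.0050), 0.61 for microglia (adjusted p = 0.0050), 0.58 for cholesterol synthesis (adjusted p = 0.0047), 0.55 for macrophages and monocytes (adjusted p = 0.0021), 0.34 for hypoxia and glycolysis (adjusted p = 0.024), 0.22 for cell cycle (adjusted p = 0.034) and 0.20 for MHC class I (adjusted p = 0.033). It gave -0.73 for type I interferon response (adjusted p = 1.3e-08), -0.68 for oligodendrocytes (adjusted p = 0.011) and -0.65 for immediate early genes (adjusted p = 6.5e-07). With an estimated correlation the smallest adjusted p of these was 0.053, for immediate early genes.

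Choroid plexus genes were higher in day 7 tumours of Pfp/Rag2 -/- hosts. An effect of host genotype at every stage is argued against by a median of 1.26 at day 14 and -0.21 at the symptomatic stage, where day 7 had -3.57. All 8 of 8 measured members differed in the same direction between the 2 Pfp/Rag2 -/- pools, by a median of 1.89, so unequal amounts of choroid plexus tissue in the dissected pools may account for the difference. An effect of genotype at day 7 alone stays open, as untested.

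Interferon-gamma response and MHC class II genes were higher in WT hosts at every stage. With the neuron level as a covariate 26 of 26 members of the interferon-gamma and MHC class II lists were called higher in WT hosts as a mean over stages, which argues against brain tissue as the whole cause, and the least favourable of cyclic loess, median scaling and no background correction also called 26 of 26. In the mean of MHC class II genes 0 of 14 tumour arrays lay out of place, which argues against a swap of 2 samples. The interferon-gamma list was called at 3 of 3 stages with an estimated correlation (largest adjusted p = 0.011), which only restates the difference, so the host genotype, or another difference between the host groups, stays open. Of 100 splits within stages, drawn from 360, only the real one called as many as 2758 genes. The highest other, with 1 WT array exchanged, called 2264, and the highest with at least 2 exchanged 1926. This argues against chance for the mean without excluding it.

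Of the genes lower in symptomatic WT hosts, 200 were so by at least 2-fold (median -1.30). Of 10 splits of the 6 symptomatic arrays, too few for a share under 0.05, only the real one gave as many as 2393 calls. The highest other gave 1 call. A lower share of tumour cells in WT hosts stays open, since host cells may also express genes of the cell line. For 608 of these the median was 0.091 and the first quartile -0.14 (0.10 and -0.12 without 14 of the 200). More brain tissue in pools of Pfp/Rag2 -/- hosts, as measured by neurons, is argued against as the whole cause by 186 of the 200 still called lower with the neuron level as a covariate, with a median of -1.21. Tissue rich in oligodendrocytes stays open. Their signal separated the hosts, at 9.47% to 11.6% of brain in WT and 14.2% to 20.3% in Pfp/Rag2 -/- pools. In cultured cells it was 10.3% and 12.9%. As a covariate it therefore cannot decide, with 101 of the 200 still called lower (median -1.07). Of the 200, 131 were lower in cultured cells than in brain. A change of expression in tumour cells, or of the host cells present, stays open too.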

How the results depend on the processing

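The fits with the neuron or the oligodendrocyte level as a covariate and with tumours only were chosen after seeing the data, and the other alternatives were set beforehand. Counts of called genes stayed within 1.5 times the main count in all 10 contrasts without background correction, with offset 50, under cyclic loess and median scaling, without a detection filter or with a strict one, with the mean of a gene's probes and with trend and robust moderation. They did so too with the replicate block, which gave 517, 2042 and 2560 genes for the host effect at day 7, day 14 and the symptomatic stage, although deviations of equally numbered pools correlated at 0.06 at day 7, 0.73 at day 14 and -0.26 to 0.09 at the symptomatic stage, so the numbers show no pairing in general. A chip block was not run because the files name no chips.

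The count for the host effect at day 7 was 63 with only the groups compared, which leaves 2 residual degrees of freedom, 287 with tumours only and 298 with a 2-fold limit. At day 14 it was 178 and 798 with only the groups compared and with a 2-fold limit, and at the symptomatic stage 691 with that limit and 1016 with the oligodendrocyte covariate. The mean over stages gave 1713 with the series matrix values (1189 higher, 524 lower), which differ in genes, scaling and background correction at once, and 482 with the 2-fold limit (432 higher, 50 lower). The difference of host effects gave 176 with the series matrix values, 175 with only the groups compared, 75 with tumours only and 535 with the neuron covariate, and the cause was not tested. The stage effect gave, in WT hosts, 4796 with the series matrix values, 55 with the neuron covariate and 2590 with the 2-fold limit, and in Pfp/Rag2 -/- hosts 214 with the covariate and 2406 with the limit. The covariate itself moves with stage. The 2-fold limit left 1932 genes for tumours against cells and 6540 for tumours against brain, where the series matrix values gave 6796, and 6803 for cells against brain.

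Leaving out single arrays gave 125 to 1255 genes for the host effect at day 7, 913 to 2386 at day 14, 1566 to 2350 at the symptomatic stage and 2106 to 2951 for their mean. It gave 31 to 769 for the difference of host effects, 4609 to 6821 and 3323 to 6760 for the stage effect in WT and Pfp/Rag2 -/- hosts, 3175 to 5332 for tumours against cells, 9677 to 10816 for tumours against brain and 9672 to 9801 for cells against brain. A group left with 1 array is assumed to vary like the others. The cause was not tested.

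Of 141 list calls 40 held with an estimated correlation. Cyclic loess ended 7, median scaling 6, the strict filter 12, fry 18 and the replicate block 3, which with new ones gave 140 calls. The neuron covariate, run on tumour contrasts only, kept 85 of their calls, ended 14 and turned 3. With it the microglia list turned to 0.25 and the neuron list to 0.025 in the stage effect of WT hosts and the neuron list to -0.016 in the symptomatic host effect, the latter 2 by construction.

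Of the named genes in the symptomatic host effect, the oligodendrocyte covariate turned Eno2 to 0.34, Gad2 to 0.53, and Cldn11 and Ugt8a, of its own list, to 0.013. P2ry13 turned to 0.072 in the stage effect of WT hosts with the neuron covariate. In the stage effect of Pfp/Rag2 -/- hosts the series matrix values turned Egr2 to -0.21 and Jun to -0.28. In tumours against cells Cd8b1 turned to 0.20 with the mean of its probes and to 1.18 with the series matrix values, its probes being called in both directions. Aspa turned to 0.31 in tumours against brain without a detection filter, which lets another probe stand for it. Signal over background limits the dim genes: 32.3% to 39.8% of probes were detected on an array, and for a probe at background only a least fold can be given.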

Other observations

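The tests on the neighbourhoods of Rag2 and Prf1 were chosen after values of 2 genes on the same chromosomes, Spint1 and Zfp365, were seen, and that on Xist after its values on the arrays were seen.

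Ramp1 and Krt8 were lower in symptomatic WT hosts, at -2.53 and -2.41 with the neuron level as a covariate. Higher in cultured cells than brain were 20.5% of the 200 genes 2-fold lower there, 25.9% of 491 2-fold higher and 42.2% of all tested.

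Xist, expressed by cells of female mice, was at background in cultured cells. In tumours of WT hosts it was higher at day 14 (1.27, adjusted p = 0.017) but not called at day 7 (0.10, adjusted p = 0.95) or at the symptomatic stage (0.77, adjusted p = 0.058). A candidate explanation is that tumours of WT hosts hold more host cells other than brain tissue. With the neuron level as a covariate Xist was higher by 0.75 (SE 0.10, adjusted p = 2.8e-04) as a mean over stages, against 0.71 without it. The sex of the mice is not given in the sources used here, so unequal numbers of female hosts could give the same value of 0.75. Ddx3y of the Y chromosome differed by -0.53 at day 14 (adjusted p = 0.078) and 0.57 at the symptomatic stage (adjusted p = 0.021), which does not settle this.

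Mice made by gene targeting may carry DNA of the donor strain around the targeted gene, whose variants could change a signal or a probe's binding. Of 11496 tested genes with a place in the annotation, the 50 on each side of Rag2 held 8 genes called at day 7 with Spint1 and Zfp365 left out, and 4.64% of 9514 windows of this size held as many (median 4, highest 18). The 8 were Serping1 (1.41), Ube2l6 (0.92), Cat (-1.06), Lmo2 (0.75), D430041D05Rik (1.88), Bbox1 (-2.04), Meis2 (1.07) and Plcb2 (1.47). Around Prf1 there were 6, and 19.4% of windows held as many, which leaves the question open there. As 2 places were tried without correction, the share at Rag2 is weak evidence, and Serping1 is also a complement gene.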
